A study of Mus musculus with 16 samples.

How the data were processed

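RNA of sorted CD24+ and CD172a+ dendritic cells was hybridized to 16 Affymetrix Mouse Gene 1.0 ST arrays. Per the labels, total RNA was isolated with an EZNA MicroElute kit, treated with TURBO DNase and amplified with the Ovation Pico WTA system. Bone marrow was grown for 9 days in 5% Flt3l and then treated with gamma interferon and with LPS for 4 hours. The time in gamma interferon is given as 16 hours in the series design and as 22 hours in the growth protocol, and which is right is not known. The deposited values are log2 signals, 1 per probe set, made by the authors with a method for background correction, normalization and summarization that is not given in the sources used here. The log2 unit was read from the values, which lie between 3.06 and 14.6 in all arrays. Within a tissue the arrays had nearly the same quartiles, while medians were 7.29 to 7.32 in the 8 spleen arrays and 6.85 to 6.92 in the 8 culture arrays, so the tissues look normalized as separate sets. Genotype and subset comparisons stay within a tissue. Culture against spleen does not, and its changes are given relative to the median gene, with quantile normalization over the 16 arrays and median centring as alternatives.

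The table held 30177 probe sets. Of these, 21789 had 1 gene symbol, 21698 of them named through their Entrez ID, 1621 had several symbols and 6767 had none. Genes were tested by their probe set with the highest mean where a gene had more than 1 (999 genes), which left 19938 genes. Probe sets with several or no symbols were left out of the tests and brought back as an alternative. No 2 arrays were duplicates. No replicate outlier test was run, since groups held 2 arrays.

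Tests used limma 3.58.1 in R 4.3.3. A fit of the 16 arrays with 1 mean per group (8 residual and 3.95 prior degrees of freedom) gave the genotype effect (KO minus WT) in each tissue and subset, the subset difference (CD24+ minus CD172a+, mean of both genotypes) in each tissue, its difference between tissues (culture minus spleen), and culture minus spleen in each subset. Array fits treated the 2 arrays of a mouse as independent. Fits on the mean of each mouse's 2 arrays gave the genotype effect in mice and its difference between tissues, and a fit on the difference between each mouse's 2 arrays gave the genotype by subset difference. Every p was 2-sided and Benjamini-Hochberg adjusted over the genes of a comparison, with a threshold of 0.05. As a check of the pairing, the correlation across genes of the group-centred values of a mouse's 2 arrays was -0.0957 in spleen WT, 0.202 in spleen KO, 0.205 in culture WT and 0.393 in culture KO. Genes are not independent replicates, so these values carry no test. WT and KO mice are different animals and were not paired.

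Before the data were examined, 31 gene lists were fixed from general knowledge, covering antigen presentation, DC subsets and maturation, interferon and LPS responses, stress, metabolism, other cell types a sort could hold, neighbours of Ciita and sex-linked genes. Listed names were matched by current symbol or, failing that, by alias. For 3 members the alias belonged to another gene (Pigq for Gpi1 in glycolysis, Tlr12 for Tlr11 in cDC1 markers, Klk1b1 for Klk1 in pDC markers). They stay in the counts given, and the lists without them are an alternative. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists of a comparison. Counts "adjusted over the list alone" adjust the genes of 1 list only. The named genes follow a rule of the same date: in genotype comparisons Ciita, all measured class II members, up to 20 genes past the threshold whose arrays do not overlap between genotypes and the 2 members of each other list with the largest change, and in subset and culture comparisons the 10 highest and 10 lowest genes and up to 4 members per list. S100a8, Ngp, Camp and Car1 levels per array, the nearest neighbours of Ciita and the 5 unfolded protein response genes lower in both KO arrays of all comparisons were chosen after their values were seen. Chromosomes and the order of genes are from RefSeq genes on GRCm38.p6. The build behind the array is not given in the sources used here, so no positions are printed.

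The array fit was tested on simulated data with 19938 genes, of which 50 each were changed by 0.5, 1, 2 and 4 on the log2 scale. For the genotype effect in cultured CD24+ cells it recovered 70, 96, 100 and 100% of them, with 12 unchanged genes called. The all-mice fit recovered 96% and the genotype by subset fit 58% of changes of 0.5, with 13 and 7 unchanged genes called. Simulated noise was independent between genes and between the 2 arrays of a mouse. The simulated fits called 195 genes for cultured CD24+ cells and 211 for all mice, against 19 and 7 in the real data. Their adjusted threshold was thus less strict, so recovery in the real data can be lower. A list shifted by -0.5 was the 1 list of 31 that camera called. Since the simulated genes were independent, this does not show how often camera calls unshifted lists whose genes are correlated.

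Alternatives fixed before the data were examined were quantile normalization, a low-signal filter (above the 40th percentile in at least 2 arrays, 13918 genes), an intensity-trended prior variance, the mean of a gene's probe sets, all probe sets, a 2-fold threshold, only 1 tissue in the fit, the mouse as a random or fixed block, the replicate number as a block, and leaving out each array or mouse in turn. Where this leaves a group with 1 array, that array is assumed to vary like the other groups. Median centring, and leaving out spleen CD24+ KO replicate 2 and cultured CD24+ KO replicate 2 together, or their mice, were added after seeing the data, as were the lists without the 3 members matched to another gene.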

Results

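Gene expression was measured on 16 Affymetrix Mouse Gene 1.0 ST arrays in classical dendritic cells (DCs) of mice that lacked Ciita (Ciita -/-, called KO here) and of mice with both copies (Ciita +/+, called WT). Ciita is the transactivator that drives transcription of the MHC class II genes, whose products present antigen to CD4 T cells. Every mouse was on the B6 strain and carried 1 GFP allele of Zbtb46, a transcription factor of the classical DC lineage. CD24+ cells, the sort used for the cDC1 subset, and CD172a+ (Sirpa+) cells, the sort used for the cDC2 subset, came from spleen or from bone marrow (BM) cultured with Flt3l and then activated with gamma interferon and LPS. The 8 groups (2 tissues, 2 subsets, 2 genotypes) held 2 arrays each. They came from 8 mice, each of which gave 1 CD24+ and 1 CD172a+ array, so each genotype had 2 mice per tissue. Array medians lay between 7.29 and 7.32 on the log2 scale in spleen and between 6.85 and 6.92 in BM culture. The number of arrays limits the precision. All changes below are log2 fold changes with their standard error (SE), from limma fits over 19938 genes, and n is 2 arrays per group unless stated.

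The series asks how many transcripts depend on Ciita in these cells. Ciita itself (probe set 10433507, chromosome 16) gave no clear difference in the spleen: its change was 0.03 ± 0.43 in CD24+ cells (adjusted p = 1.000), with means of 11.04 in KO and 11.01 in WT, and -0.23 ± 0.43 in CD172a+ cells (adjusted p = 1.000). In BM culture the mean was 8.92 ± 1.10 (SD, n = 2) in KO and 10.68 ± 0.25 in WT CD24+ cells, a change of -1.76 ± 0.43 (adjusted p = 0.410). In cultured CD172a+ cells it was 7.76 ± 0.84 in KO and 10.39 ± 0.33 in WT, a change of -2.63 ± 0.43 (adjusted p = 0.0870). The labels do not say which part of the gene was deleted, so the spleen signal of this probe set does not tell whether an intact transcript was present. The class II genes were lower in each KO array than in each WT array of the same group pair, H2-Ea excepted, and thus matched the genotype labels.

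In spleen CD24+ cells, MHC class II transcripts made up most of the genes lower in KO. Of the 9 measured members of the class II list, 7 fell (all 9 adjusted over the list alone): H2-Ob (-2.41 ± 0.28), H2-Ab1 (-1.91 ± 0.24), H2-Eb1 (-1.89 ± 0.21), H2-Oa (-1.74 ± 0.13), H2-Eb2 (-1.58 ± 0.17), H2-DMa, a subunit of the peptide exchanger H2-DM, (-0.84 ± 0.10), and Cd74, the invariant chain, (-0.64 ± 0.07). H2-Aa, the alpha chain that pairs with H2-Ab1, stayed at a mean of 13.24 in KO against 13.75 in WT (-0.51 ± 0.13, adjusted p = 0.653). H2-Ea, at a signal of 5.72 and 5.99, gave -0.27 ± 0.08 (adjusted p = 0.853). Outside the list, 4930503L19Rik (-1.08), Tpm2, a tropomyosin (-0.91), Derl3, a component of endoplasmic reticulum (ER) associated degradation (-0.61), and B230217C12Rik (-0.61) fell, and Alpl, an alkaline phosphatase, rose by 0.51. The calls of Alpl and H2-Ab1 were lost without any 1 of the 4 arrays of this comparison. In all, 12 genes passed an adjusted p of 0.05, 1 higher and 11 lower, 6 of them by at least 2-fold. The count depended on single arrays: it was 1 without WT replicate 1, 1 without WT replicate 2, 2 without KO replicate 2 and 35 without KO replicate 1, and H2-Oa was the gene that passed in all 4 cases.

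In spleen CD172a+ cells class II genes again led the loss. Of the 9 list members, 8 fell (9 adjusted over the list alone), H2-Ea being the exception. H2-Eb1 fell by 3.14 ± 0.21 (8.84-fold), H2-Eb2 (-2.69 ± 0.17), H2-Aa (-2.61 ± 0.13, adjusted p = 2.161e-06), H2-Ob (-2.59 ± 0.28), H2-Ab1 (-2.54 ± 0.24), H2-DMa (-1.23 ± 0.10), H2-Oa (-1.08 ± 0.13) and Cd74 (-0.83 ± 0.07). The nonclassical class I gene H2-M2, which lies in the MHC but belongs to no class II complex, fell (-1.74 ± 0.16). BC051142 (-1.09), Tmem231, a protein of the ciliary transition zone (-0.96), Tlr8, an endosomal RNA sensor (-0.90), Tspyl5 (-0.86), B230217C12Rik (-0.84) and Trem3, a myeloid surface receptor (-0.80), also fell, and Gp2, a glycoprotein that binds bacterial pili, rose by 1.02 ± 0.15. In all, 16 genes passed, 1 higher and 15 lower, 10 of them by at least 2-fold. Without single arrays of this comparison the count stayed between 13 and 21, and 11 of the 16 calls held in all 4 cases. H2-Oa was lost without KO replicate 2 or WT replicate 2, Tlr8 without either KO array, Tspyl5 without KO replicate 1 or WT replicate 2, and Trem3 and Gp2 in all 4 cases.

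**Figure D1:**
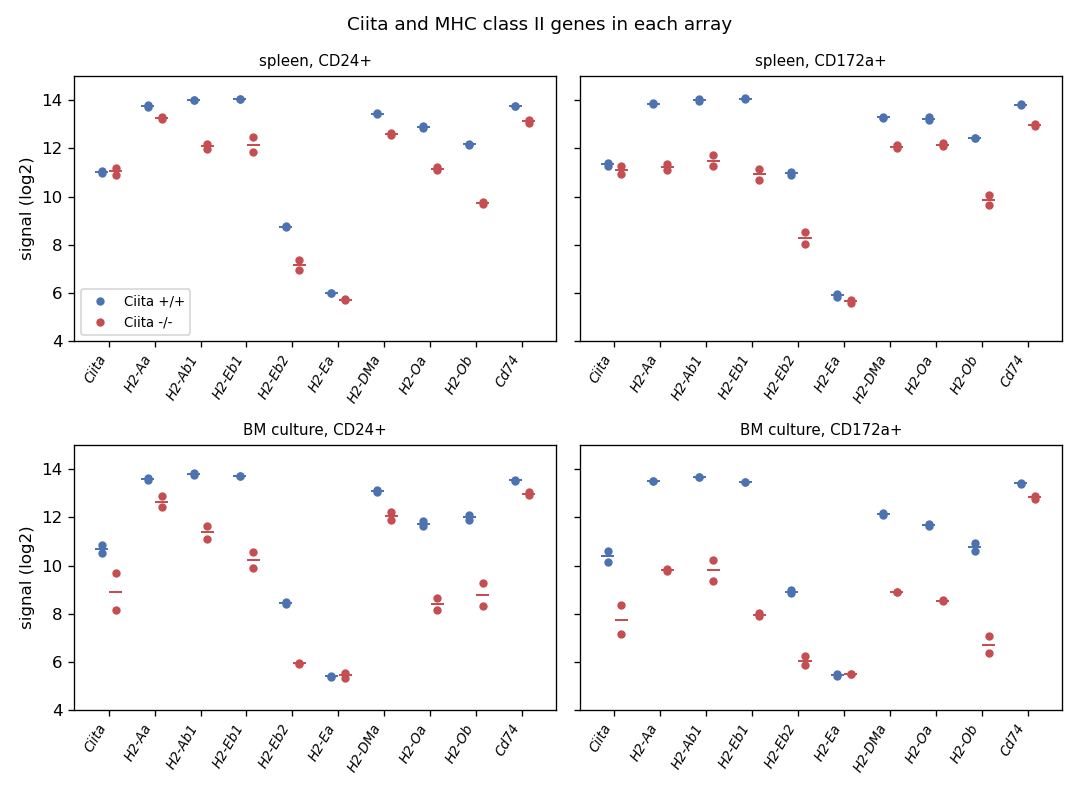
Signal (log2, vertical axis) of Ciita and the 9 measured MHC class II list members in each array, with 1 panel per tissue and subset, points for single arrays (2 WT and 2 KO per panel) and short lines at the group means. H2-Aa lies at a KO mean of 13.24 in spleen CD24+ cells but 11.23 in spleen CD172a+ cells, and at 12.65 against 9.83 in BM culture.

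In cultured, activated CD24+ cells, class II transcripts and a set of ER chaperone and folding genes were lower in KO. Of the 9 class II members, 8 fell (8 adjusted over the list alone): H2-Eb1 (-3.49 ± 0.21), H2-Oa (-3.32 ± 0.13), H2-Ob (-3.21 ± 0.28), H2-Eb2 (-2.49 ± 0.17), H2-Ab1 (-2.44 ± 0.24), H2-DMa (-1.05 ± 0.10), H2-Aa (-0.93 ± 0.13, adjusted p = 0.0120) and Cd74 (-0.55 ± 0.07). Creld2 fell by 2.04 ± 0.20 (adjusted p = 5.821e-04), Pdia4, a protein disulfide isomerase, (-1.93 ± 0.15, adjusted p = 7.964e-05), and Sdf2l1, a partner of the chaperone BiP, (-1.87 ± 0.14, adjusted p = 7.964e-05). Hyou1 (adjusted p = 0.00263), the ubiquitin ligase Syvn1 (-0.99), Hsp90b1 (-0.97), Dnajc3 (-0.80) and Manf (-0.78) are further ER proteins that fell. Vmn2r90, annotated as a vomeronasal receptor, fell (-2.10 ± 0.20), while Clec7a, the beta-glucan receptor dectin-1, rose by 0.97 ± 0.14 and Rtcb, an RNA ligase, by 0.41 ± 0.06. In all, 19 genes passed, 2 higher and 17 lower, 11 of them by at least 2-fold. The count was 4 when the fit held the BM culture arrays alone, 10 without WT replicate 2 and 1269 without KO replicate 1, which left KO replicate 2 as the lone KO array of this group. KO replicate 2 stood apart from its group: Xcr1, a cDC1 marker, read 9.58 there against 10.4 to 10.9 in the other 3 CD24+ culture arrays, and Sirpa read 9.17 against 8.36 to 8.43. Creld2, Pdia4, Sdf2l1, Vmn2r90, H2-Eb1, H2-Oa, H2-Ob, H2-Eb2, H2-Ab1 and H2-DMa passed whichever of the 4 arrays was left out. Those fits still took the spread from all groups. With the culture arrays alone 4 genes passed, so most of these calls needed the spleen arrays in the fit.

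Cultured CD172a+ cells held the widest genotype change of the 4 comparisons, in H2-Eb1. Again 8 of 9 members fell (8 adjusted over the list alone): H2-Eb1 (-5.51 ± 0.21, 45.7-fold, adjusted p = 5.267e-08), H2-Ob (-4.05 ± 0.28), H2-Ab1 (-3.87 ± 0.24), H2-Aa (-3.69 ± 0.13, 12.9-fold, adjusted p = 1.835e-08), H2-DMa (-3.24 ± 0.10), H2-Oa (-3.14 ± 0.13), H2-Eb2 (-2.86 ± 0.17) and Cd74 (-0.58 ± 0.07). The C-type lectin receptors Clec4e (Mincle, -1.50 ± 0.21) and Clec4a1 (-1.05 ± 0.14) fell, as did Dexi (-0.85 ± 0.09), the tested gene next to Ciita on chromosome 16 in the mouse assembly GRCm38.p6. Eif4g3, a translation initiation factor, rose by 0.49 ± 0.07. In all, 12 genes passed, 1 higher and 11 lower, 9 of them by at least 2-fold. The count was 7 when the fit held the BM culture arrays alone, 7 without KO replicate 2 and 45 without KO replicate 1. It was also 31 without either KO array of the cultured CD24+ group, which shares the estimate of the spread. Eif4g3 was lost without any 1 of the 4 arrays of this comparison, Cd74 without either WT array or KO replicate 2, Clec4e and Clec4a1 without WT replicate 1 or KO replicate 2, and Dexi without KO replicate 2. The other 7 class II calls held in all 4 cases.

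Beyond class II, no member of 27 of the 31 gene lists fixed before the data were examined passed the threshold in the 4 genotype comparisons of a tissue and subset. These include 13 genes reported elsewhere as Ciita targets, of which 0 passed by limma (11 of 52 gene and comparison pairs had an unadjusted p under 0.05, 6 passed adjusted over the list alone). Camera and the directional test of fry did not call this list. The mixed test of fry, which lets members move both ways, called it in spleen CD24+ cells (adjusted p = 7.444e-05) and spleen CD172a+ cells (adjusted p = 0.0130). Among them Btn2a2, a butyrophilin, gave -0.45 ± 0.10 in spleen CD172a+ cells (adjusted p = 0.323) and Plxna1 gave 0.45 ± 0.12 in cultured CD172a+ cells (adjusted p = 0.480). Of the 7 listed factors that bind class II promoters with Ciita (members of the RFX and NF-Y complexes, and Creb1), 0 passed (3 of 28 pairs at an unadjusted p under 0.05, 3 adjusted over the list alone), and Rfx5 gave between -0.40 and -0.21 in the 4 comparisons. Of the 10 genes of class II peptide loading and turnover, such as the cathepsins and Ifi30, 0 passed (2 of 40 pairs at an unadjusted p under 0.05, 0 adjusted over the list alone). Derl3, on the plasma cell list, 5 unfolded protein response genes and Dexi were the list members outside class II that passed in these 4 comparisons.

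Set tests asked whether lists moved as a whole against all other genes. Camera with a preset correlation called 24 of the 124 list and comparison pairs, and 7 held with an estimated correlation. The class II list was lower in all 4 comparisons, with adjusted p of 0.00619, 0.00321, 0.00908 and 0.00230 with an estimated correlation in the order above. The unfolded protein response list, genes that cells induce when ER folding is overloaded, was lower in cultured CD24+ KO cells (median -0.68, 5 of 15 lower, 10 adjusted over the list alone, adjusted p = 0.0206 with an estimated correlation). Without KO replicate 1 or KO replicate 2 of that group the median was -0.855 and -0.52, and the call with an estimated correlation was lost. It held without either WT array. The type I interferon list was higher in spleen CD172a+ KO cells (median 0.37, adjusted p = 0.0338 with an estimated correlation), where 0 of 18 genes passed over all genes and 11 were higher adjusted over the list alone. Ifit3 gave 0.87 ± 0.15 (adjusted p = 0.0741) and Ifit2 0.67 ± 0.14 (adjusted p = 0.240). Without 1 of the 4 arrays the list median ranged from 0.27 to 0.41, while the call with an estimated correlation was lost each time. The call thus rested on every array, and the direction did not. The pan-cDC identity list was lower in cultured CD172a+ KO cells (median -0.33, 0 of 15 genes over all genes, 2 adjusted over the list alone, adjusted p = 0.0391 with an estimated correlation), with Spi1 (PU.1) at -0.79 ± 0.24 (adjusted p = 0.554). This call too was lost when any 1 of the 4 arrays was left out, and without KO replicate 2 the list median was -0.13.

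The other camera calls were lost with an estimated correlation. In spleen CD24+ KO cells these were the type I interferon list (median 0.23, 1 of 18 higher adjusted over the list alone, adjusted p = 0.378 with an estimated correlation) and the unfolded protein response list (median -0.22, 4 of 15 lower adjusted over the list alone, adjusted p = 0.378). The others there were the cell cycle list (median 0.20, 0 of 19, adjusted p = 0.389) and the neutrophil list (median 0.85, 3 of 15 higher adjusted over the list alone, adjusted p = 0.378). S100a8 and Ngp were highest in KO replicate 2, at 10.1 and 10.5, and lowest in WT replicate 2, at 6.21 and 5.91. They read 7.91 and 7.63 in KO replicate 1 and 8.06 and 8.68 in WT replicate 1, so the genotypes overlapped. In cultured CD24+ KO cells the calls lost were DC maturation (median 0.20), LPS and NF-kB response (0.07), cholesterol synthesis (-0.51, 4 of 14 lower adjusted over the list alone), each with an adjusted p of 0.287 with an estimated correlation. Also lost were cDC1 markers (-0.17, adjusted p = 0.514) and cell cycle (-0.19, adjusted p = 0.564). In cultured CD172a+ KO cells they were the unfolded protein response (median -0.16), cDC1 (-0.06) and cDC2 (-0.01) markers, each with an adjusted p of 0.508 with an estimated correlation. Class I presentation (-0.04, adjusted p = 0.498) was another, as were gamma interferon response (-0.03), glycolysis (-0.20), cholesterol synthesis (-0.25) and ribosomal proteins (-0.06), each with 0.673. The largest member change of the gamma interferon list there was that of Ciita itself.

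**Figure D2:**
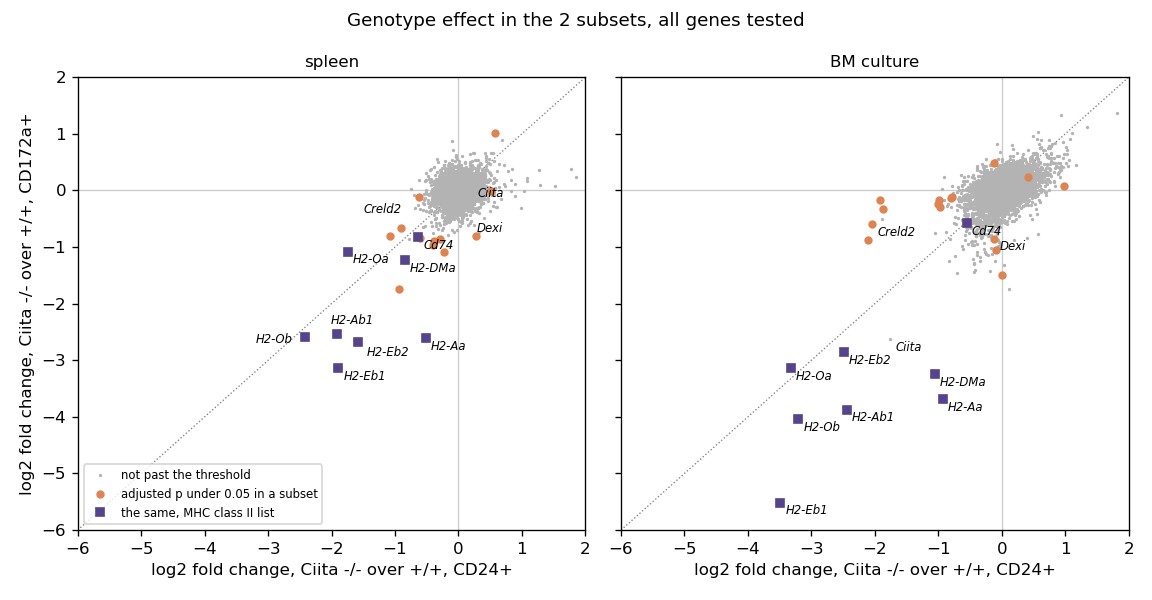
Log2 fold change of KO over WT in CD24+ cells (horizontal axis) and CD172a+ cells (vertical axis) for the 19938 genes tested, in spleen and in BM culture, with genes past an adjusted p of 0.05 in a subset in colour, MHC class II list members as squares, selected genes named, and a dotted line of equal change. H2-Aa sits at -0.51 and -2.61 in spleen and at -0.93 and -3.69 in BM culture, far from that line.

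With the 2 arrays of a mouse averaged, so that mice were the units, class II genes again led. In spleen mice 15 genes passed (2 higher, 13 lower, n = 2 mice per genotype), headed by H2-Eb1 (-2.52 ± 0.18), H2-Ob (-2.50 ± 0.24), H2-Ab1 (-2.23 ± 0.20) and H2-Eb2 (-2.13 ± 0.08). In BM culture mice 13 genes passed, 0 higher and 13 lower (1544 genes at an unadjusted p under 0.05), headed by H2-Eb1 (-4.50 ± 0.18), H2-Ob (-3.63 ± 0.24), H2-Oa (-3.23 ± 0.10) and H2-Ab1 (-3.15 ± 0.20). Creld2 (-1.32 ± 0.10), Sdf2l1 (-1.10 ± 0.09) and Vmn2r90 (-1.49 ± 0.14) were also lower. Over all 8 mice, 4 per genotype, 7 genes passed and all were lower: H2-Eb1 (-3.51 ± 0.36), H2-Ob (-3.06 ± 0.25), H2-Ab1 (-2.69 ± 0.21), H2-Eb2 (-2.40 ± 0.11), H2-Aa (-1.94 ± 0.14), Cd74 (-0.65 ± 0.05) and Map7d1, a microtubule-binding protein (-0.34 ± 0.04, adjusted p = 0.0417). The spleen count was 1 without WT replicate 1 or WT replicate 2, 3 without KO replicate 2, 7 without KO replicate 1 and 8 without either WT mouse of the culture. The BM culture count was 1341 without KO replicate 1, 5 without WT replicate 2 and 5 with the culture mice alone in the fit, and the count over all mice was 4 without BM culture WT replicate 1 and 11 without BM culture KO replicate 2.

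For 4 class II genes the loss differed between the subsets. A test of the genotype by subset difference, on the difference between each mouse's 2 arrays (n = 4 mice per genotype), found these 4 genes and no others, all with a smaller loss in CD24+ than in CD172a+ cells. Averaged over the 2 tissues, H2-Aa differed by 2.43 ± 0.10 (adjusted p = 4.508e-05), H2-Eb1 by 1.64 ± 0.11 (adjusted p = 0.00167), H2-DMa by 1.29 ± 0.09 (adjusted p = 0.00167) and H2-Ab1 by 1.03 ± 0.10 (adjusted p = 0.0201). By the changes per tissue given above, the gap between the subsets was wider in culture than in spleen for all 4 genes, most of all for H2-DMa. Whether this gap differed between the tissues was not tested. The other class II genes had no call in the genotype by subset test: H2-Eb2 gave 0.74 ± 0.18 (adjusted p = 0.751), H2-Ob 0.51 ± 0.10 (adjusted p = 0.595), Cd74 0.11 ± 0.07 (adjusted p = 0.944) and H2-Oa -0.42 ± 0.11 (adjusted p = 0.807). With 1 mouse left out, 3 or 4 of these 4 genes still passed. The WT means of these genes lay near the top of the array range, H2-Aa at 13.75 and 13.84 in spleen CD24+ and CD172a+ cells. The class II list as a whole had a median difference of 0.74, and its camera call (adjusted p = 1.140e-10) was lost with an estimated correlation (adjusted p = 0.120). The unfolded protein response list had a median difference of -0.23, and its camera call (adjusted p = 1.420e-09) was lost with an estimated correlation (adjusted p = 0.157).

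Between tissues, H2-Oa was the gene whose loss differed, being larger in culture (-1.82 ± 0.14, adjusted p = 0.0411, n = 2 mice per genotype and tissue). Tissue here goes together with culture, activation and the sex of the mice, so their parts cannot be told apart. H2-Eb1 (-1.98 ± 0.25, adjusted p = 0.344) and H2-DMa (-1.11 ± 0.10, adjusted p = 0.0900) did not pass. In limma this call ended with quantile normalization (0 genes, 1019 at an unadjusted p under 0.05) and when any 1 of the 4 spleen mice or 1 of the 2 WT culture mice was left out (0 genes, 591 to 943 at an unadjusted p under 0.05). By contrast, 688 genes passed without BM culture KO replicate 1.

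**Figure D3:**
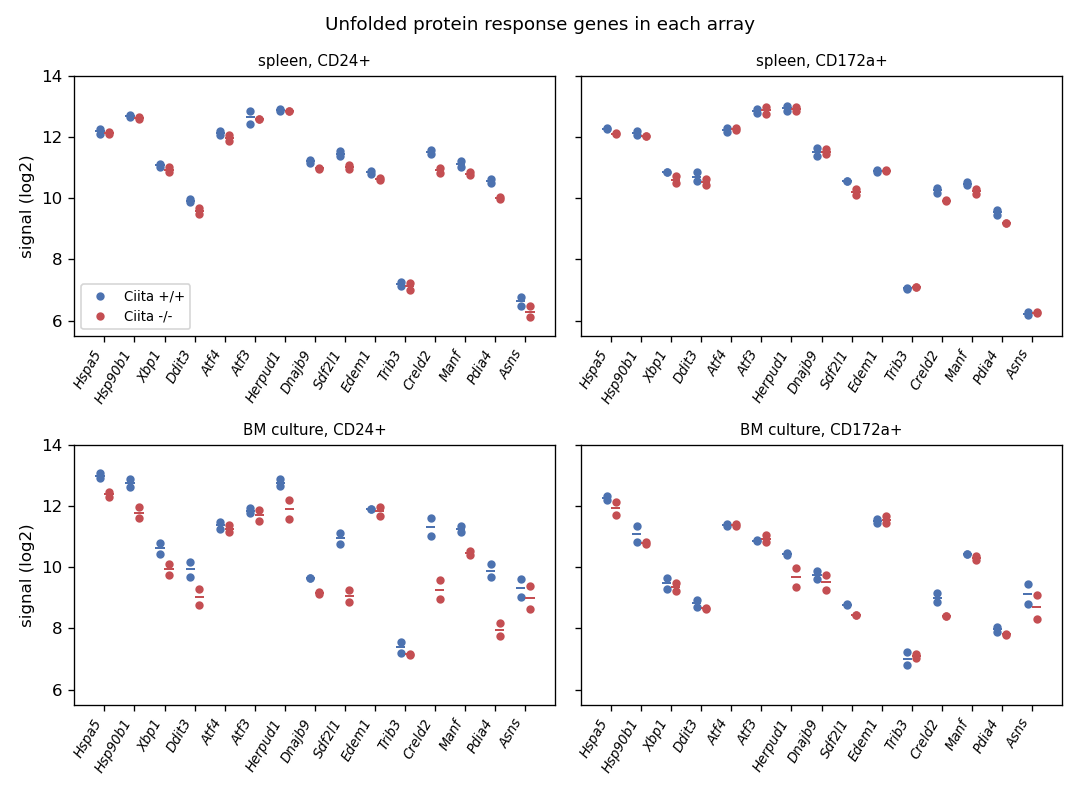
Signal (log2, vertical axis) of the 15 unfolded protein response list members in each array, with 1 panel per tissue and subset, points for single arrays (2 WT and 2 KO per panel) and short lines at the group means. Creld2, Pdia4 and Sdf2l1 are lower by -2.04, -1.93 and -1.87 in cultured CD24+ KO cells, and smaller gaps of the same sign stand in the other panels.

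Within the unfolded protein response list, Creld2, Sdf2l1, Pdia4, Hsp90b1 and Manf read lower in both KO arrays than in both WT arrays in each of the 4 comparisons. None of these 5 passed over all 8 mice: Creld2 gave -0.89 ± 0.16 (adjusted p = 0.390), Pdia4 -0.75 ± 0.11 (adjusted p = 0.188), Sdf2l1 -0.75 ± 0.14 (adjusted p = 0.390), Manf -0.37 ± 0.05 (adjusted p = 0.146) and Hsp90b1 -0.36 ± 0.13 (adjusted p = 0.856). As a list in all mice the median was -0.30, and the camera call (adjusted p = 6.385e-15) was lost with an estimated correlation (adjusted p = 0.358).

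The subsets were compared over both genotypes (n = 4 arrays per subset and tissue). In spleen, CD24+ cells had the cDC1 profile and CD172a+ cells the cDC2 profile. Of 20 cDC1 markers, 19 were higher in CD24+ cells (20 adjusted over the list alone, adjusted p = 0.00575 with an estimated correlation). The widest were the chemokine receptor Xcr1 (5.41 ± 0.20), Rab7b (5.28 ± 0.19), Ifi205 (5.27 ± 0.08) and the dead-cell receptor Clec9a (4.90 ± 0.10). Of 18 cDC2 markers, 15 were lower and 2 higher (15 and 2 adjusted over the list alone, adjusted p = 0.00575 with an estimated correlation), among them Clec4a4 (-5.86 ± 0.11), the RNA sensor Tlr7 (-5.48 ± 0.20), Sirpa (-3.90 ± 0.15) and Itgam (-3.26 ± 0.17). The widest differences outside these lists were Gpr141b (5.99), Plpp1 (45.2-fold), P3h2 (5.31) and P2ry14 (4.96) in favour of CD24+ cells, and Mmp12 (-5.11), Dscam (-4.71), Rtp4 (-4.63) and Bmp2 (-4.24) in favour of CD172a+ cells. Of 18 type I interferon genes, 14 were lower and 2 higher in CD24+ cells (14 and 3 adjusted over the list alone, camera adjusted p = 2.358e-11), with Oas2 at -3.46 and Ddx58 at an adjusted p of 1.358e-10. This list call was lost with an estimated correlation (adjusted p = 0.0898). Il12b (2.78 ± 0.07) and Cxcl9 (3.26 ± 0.11) were higher in CD24+ cells, but their lists did not go that way. Of 19 LPS and NF-kB genes 2 were higher and 9 lower (3 and 9 adjusted over the list alone), and the camera call as lower (adjusted p = 0.0114) was lost with an estimated correlation (adjusted p = 0.183). Of 15 gamma interferon genes 6 were higher and 4 lower (6 and 5 adjusted over the list alone, camera adjusted p = 0.927). In all, 5793 genes passed, 3113 higher and 2680 lower in CD24+ cells, and 838 of them differed by at least 2-fold.

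After culture and activation the cDC1 profile stayed visible, while tests of the cDC2 list differed in their result. Of 20 cDC1 markers, 17 were higher and 1 lower in CD24+ cells (17 and 1 adjusted over the list alone, adjusted p = 0.0167 with an estimated correlation), with Clec9a at 3.96 ± 0.10, Xcr1 at 3.93 ± 0.20 and Naaa at 3.89 ± 0.12. Of 18 cDC2 markers, 7 were lower and 3 higher (the same numbers adjusted over the list alone), and the list was not called by camera (adjusted p = 0.207) but was called as lower by fry (adjusted p = 0.00249). Sirpa (-2.64 ± 0.15) and S100a4 (-2.87 ± 0.15) were lower, but Clec12a (2.50 ± 0.31) and Rbpj (2.04 ± 0.09) were higher in CD24+ cells. The pan-cDC list was higher in CD24+ cells (9 of 15 higher and 3 lower, 10 and 3 adjusted over the list alone, adjusted p = 0.0167 with an estimated correlation), with Itgax (CD11c) at 2.62 ± 0.10. Immediate early and heat shock genes were higher too (8 of 17, 8 adjusted over the list alone, adjusted p = 0.0267 with an estimated correlation). Unfolded protein response genes (11 of 15 higher, 11 adjusted over the list alone), the glycolysis list (12 of 15 higher and 1 lower, 12 and 1 adjusted over the list alone) and class II genes (5 of 9 higher and 0 lower, 6 and 1 adjusted over the list alone) gave camera calls that were lost with an estimated correlation (adjusted p = 0.145, 0.315 and 0.443). The class II counts average both genotypes. For H2-Aa, H2-Ab1, H2-Eb1 and H2-DMa the WT mean was higher in CD24+ cells by 0.07, 0.12, 0.24 and 0.96. The lowest CD24+ KO array lay above the highest CD172a+ KO array by 2.55, 0.87, 1.88 and 2.97. For these genes the subset difference was thus larger in KO than in WT cells. One of the 15 members of the glycolysis list, Pigq, is no glycolysis gene but was matched through an alias, and without it 12 of 14 were higher (adjusted p = 0.202 with an estimated correlation). Lyz2 (lysozyme, 4.59 ± 0.19), the ectonucleotidase Entpd1 (4.28 ± 0.10) and Ctla2b (4.26 ± 0.22) led in CD24+ cells, and Rtp4 (-3.88 ± 0.11) and Plekhs1 (-3.20 ± 0.14) in CD172a+ cells. In all, 4966 genes passed, 2233 higher and 2733 lower in CD24+ cells, and 627 of them differed by at least 2-fold.

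A direct test of whether the subset difference itself changed with tissue found 5630 genes, 2502 with a more positive and 3128 with a more negative difference in culture. Gpr141b (-5.78 ± 0.12), Lima1 (-4.75 ± 0.24), Ifi205 (-4.64 ± 0.11) and Gprc5c (-4.39 ± 0.35) shifted toward CD172a+ cells in culture. Mmp12 (5.02 ± 0.13), Tespa1 (4.82 ± 0.28), Clec4a4 (4.79 ± 0.15), Hpgds (4.52 ± 0.32), Dscam (4.51 ± 0.08) and Lyz2 (4.37 ± 0.27) moved the other way. Ifi205 rose in cultured over splenic CD172a+ cells by 5.29 relative to the median gene, and Irf8, the cDC1 transcription factor, by 4.47.

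Activated culture cells were compared with spleen cells within each subset (n = 4 arrays per side). The arrays of the 2 tissues did not share a scale: the median gene was lower in culture by -0.34 in CD24+ and -0.28 in CD172a+ cells, and changes here are given relative to that median. Interferon and DC maturation lists rose in both subsets. In CD24+ cells 18 of 18 type I interferon genes, 12 of 15 gamma interferon genes and 17 of 18 DC maturation genes were higher as deposited (18, 12 and 17 adjusted over each list alone) and 0, 1 and 0 lower (0, 2 and 0), with adjusted p of 0.00910, 0.00910 and 0.0101 with an estimated correlation. In CD172a+ cells these counts were 17 of 18, 13 of 15 and 16 of 18 (17, 13 and 16 adjusted over each list alone), with 1, 1 and 0 lower, and the p were 0.0356, 0.0239 and 0.0324. Iigp1, an interferon-induced GTPase, rose by 6.18 in CD24+ and 7.24 in CD172a+ cells, Il6 by 6.15 and 6.78, Ifit2 by 5.44 and 4.41, Fscn1 by 4.10 and 4.42 and the interleukin 23 receptor Il23r by 5.07 and 6.32. Class I presentation genes rose (9 of 15 and 10 of 15 as deposited, with 2 and 1 lower, the same numbers adjusted over the list alone, adjusted p = 0.00910 and 0.0239 with an estimated correlation), with Nlrc5, the class I transactivator, at 1.71 and 2.54 and Tapbp at 1.92 and 2.10. LPS and NF-kB genes were called in CD24+ cells (14 of 19 higher and 4 lower, 14 and 5 adjusted over the list alone, adjusted p = 0.00910 with an estimated correlation), and in CD172a+ cells the call was lost (10 of 19 higher and 7 lower, 10 and 7 adjusted over the list alone, adjusted p = 0.0540).

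Among the lowest genes in culture were Adgre5 (CD97), at -6.02 in CD24+ and -6.60 in CD172a+ cells, Egr2 at -5.26 and -6.28, Nr4a1 at -4.90 and -6.17 and Cxcr4 at -4.95 and -5.38. Of 17 immediate early and heat shock genes, Egr2 among them, 16 in CD24+ and 17 in CD172a+ cells were lower as deposited (16 and 17 adjusted over the list alone). They were listed as genes that rise with cell handling, and whether handling had a part in this difference was not tested. That list held with an estimated correlation in CD172a+ cells (adjusted p = 0.0487) and not in CD24+ cells (adjusted p = 0.210). Of 19 cell cycle genes 18 were lower in each subset (18 adjusted over the list alone) and 1 higher in CD172a+ cells, with Ccnb2 at -2.58 and -3.34, but the camera calls were lost with an estimated correlation (adjusted p = 0.425 and 0.426). The cDC2 markers Cd209a (-5.11), Clec4a4 (-4.97) and Cd4 (-3.86) were lower in cultured CD172a+ cells, and the cDC2 list gave an adjusted p of 0.0540 with an estimated correlation (17 of 18 lower, 17 adjusted over the list alone). Sex differed between the tissues: Xist read between 11.8 and 12.4 in the spleen arrays and between 4.98 and 5.29 in the culture arrays, while Eif2s3y read at most 4.00 in spleen and at least 8.15 in culture, so this comparison joins tissue, culture, activation and sex.

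In all, 15762 genes passed in CD24+ cells and 15312 in CD172a+ cells (4017 and 4210 of them by at least 2-fold). Of these, 17.4% and 21.6% were higher as deposited. With each array centred on its median, an alternative added after seeing the data, 8823 genes were higher and 6221 lower in CD24+ cells and 9313 and 6201 in CD172a+ cells. Quantile normalization over all arrays also turned the balance, with 7931 higher and 6769 lower genes in CD24+ cells and 8564 and 6498 in CD172a+ cells, so the numbers of higher and lower genes depended on the scaling.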

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

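All tests of explanations and all counts of splits in this part were chosen after the results were seen.

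The loss of MHC class II transcripts differed between the subsets for 4 genes by a test of the difference itself. Averaged over the 2 tissues, it was smaller in CD24+ than in CD172a+ cells by 2.43 for H2-Aa, 1.64 for H2-Eb1, 1.29 for H2-DMa and 1.03 for H2-Ab1 (log2). Dependence on 1 mouse is argued against, since with each of the 8 mice left out at least 3 of the 4 genes stayed past the threshold. A signal ceiling cannot be told apart from a true difference in size: WT CD24+ means of these genes lay at most 1.22 below the mean highest value of their arrays, so true folds could be wider than those read. Class II transcription kept without Ciita in CD24+ cells cannot be told apart from these either: the lowest CD24+ KO array lay above the highest CD172a+ KO array by 0.27 or more for the 4 genes in both tissues, but WT means of the subsets differed by at most 0.96, so this gap restates the difference in loss. In a fit with tissue as an added term the real count was 2, and 1 of 34 splits, the real one, gave as many (highest other 1), but splits that exchange mice within a tissue number 18 (highest other 1), too few for a share under 0.05.

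Unfolded protein response genes were lower in cultured CD24+ KO cells. Admixture of CD172a+ cells, which have less of these transcripts, is argued against as the whole cause: in KO replicate 1 the 7 members that differ by more than 1 between the subsets stood 56.4% of the way from the CD24+ to the CD172a+ WT level (median), against -0.4% for 21 subset markers, and in KO replicate 2 these were 95.9% and 18.2%. That replicate holds some CD172a-like signal, and leaving it out gave a list median of -0.52. Plasma cells or plasmacytoid DCs in the WT arrays are argued against, since plasma cell markers outside the list, Derl3 (-0.28) included, changed by a median of 0.0023 (SD 0.27, 6 genes) and pDC markers by 0.0130 (SD 0.183, 14 genes, or 0.01 for 13 without Klk1b1, matched through an alias), against -0.68 for the list. Of the 7 plasma cell markers, which include Xbp1 of both lists, 2 were lower adjusted over the list alone, and neither camera (adjusted p = 0.249) nor fry (adjusted p = 0.121, unadjusted 0.0117) called them as a list. Whether Ciita loss lowers these genes in CD24+ cells at large cannot be told apart from a difference between these few culture mice: in spleen CD24+ cells of other mice the list median was -0.22, a call lost with an estimated correlation.

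The genotype effect of 1 gene differed between tissues, H2-Oa, by -1.82 on the log2 scale. The subset difference differed between tissues for 5630 genes. The 10 widest were Gpr141b (-5.78), Mmp12 (5.02), Tespa1 (4.82), Clec4a4 (4.79), Lima1 (-4.75), Ifi205 (-4.64), Hpgds (4.52), Dscam (4.51), Gprc5c (-4.39) and Lyz2 (4.37). Sex, culture and activation all go with tissue in both comparisons.

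Splits were counted in fits that pool the 2 genotypes or keep tissue as a term, so their real counts differ from those of the report. For the genotype effect in all mice, 1 of 34 splits, the real one with 7 genes, gave as many, and the highest other gave 1, or 0 among the 18 splits that exchange mice within a tissue. For the spleen subset difference it was 1 of 35 (5950 genes, highest other 8), and among the 8 splits that part every mouse's 2 arrays the highest other gave 0. For the culture subset difference it was 1 of 35 (4913 genes). There the highest other gave 1405 by exchanging CD24+ KO replicate 2 with CD172a+ WT replicate 2, while among the 8 splits that part every mouse the highest other gave 0. The 1405 goes with a structure of the samples or with the part of the real grouping that this split keeps. The 18 and 8 splits that keep to the design are too few for a share under 0.05. For the subset by tissue difference it was 1 of 100 (5750 genes, highest other 1384), and 1 of 100 again among splits that part every mouse (highest other 3199). Splits that keep part of the real grouping can give high counts from the real difference alone, and a structure of the samples was not tested. For culture against spleen it was 1 of 35 in CD24+ cells (15806 genes, highest other 3) and 1 of 35 in CD172a+ cells (15328 genes, highest other 2). The splits of culture against spleen used the deposited values, whose scale differs between the tissues. Only the real split set the scales fully apart, so these counts do not tell a difference of expression from one of scale. The subset by tissue splits also broke up the subset difference itself, so they do not decide whether chance gives such a count. Chance cannot be excluded for the number of lists that camera called with its preset correlation: 6 of 35 splits gave at least the 17 list calls of the subset difference (highest other 23), and 5 of 35 at least the 25 of culture against spleen (highest other 27).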

How the results depend on the processing

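The alternatives were fixed before the data were examined, except median centring, leaving out the arrays (or mice) that stand apart and the lists without the 3 members matched to another gene, which were chosen after seeing the data. A cause is named only where the alternative's construction gives one, and otherwise the cause was not tested. A 2-fold threshold, which by construction passes fewer genes, gave 6, 10, 11 and 8 genes for the genotype effect in spleen CD24+, spleen CD172a+, cultured CD24+ cells and spleen mice. It gave 838, 627 and 1214 for the subset difference in spleen, in culture and between tissues, and 4017 and 4210 for culture against spleen. All probe sets, with more features tested, gave 21 and 25 for the genotype effect in spleen CD24+ and CD172a+ cells. For the genotype by tissue difference quantile normalization gave 0, the trended prior 2, all probe sets 2 and leaving out the mice that stand apart 2. With the culture arrays alone the genotype effect gave 4 in CD24+ cells, 7 in CD172a+ cells and 5 in mice, while with the spleen arrays alone, as few samples, it gave 10, 18 and 17, so the cause was not tested. Leaving out the arrays that stand apart gave 28 in spleen CD172a+, 12 in cultured CD24+ and 25 in cultured CD172a+ cells, and 11 for all mice. WT and KO mice share only a number: with it as a replicate block the genotype effect gave 1 in spleen mice, 5 in culture mice and 1 in all mice, and 9, 18, 16 and 12 in the 4 array comparisons. The correlation of residuals across genes between mice of 1 number was -0.0881, 0.0419, -0.555 and -0.0760. Lists called numbered 7 (estimated correlation) and 8 (fry) for the genotype effect, 5 and 33 for the subset difference, and 10 and 62 for culture against spleen, fry testing another hypothesis. Without the 3 members matched to another gene camera called the same 24, 18 and 26. The direction of the list calls of culture against spleen depended on the scaling. Camera called 17 as higher and 9 as lower with the deposited values. With quantile normalization these were 12 and 19, and with median centring 11 and 15, and 21 and 19 of the calls were shared with the deposited values. With 1 array or mouse left out the counts ran from 1 to 35 and from 13 to 21 in spleen CD24+ and CD172a+ cells, 10 to 1269 and 7 to 45 in cultured ones, 1 to 18 in spleen mice, 5 to 1341 in culture mice, 4 to 11 in all mice, 0 to 688 for genotype by tissue, and 3 to 6 for genotype by subset. They ran from 4783 to 6542, 3849 to 5866 and 4814 to 6480 for the subset difference in spleen, in culture and between tissues, and from 15073 to 15792 and 14606 to 15550 for culture against spleen. Lists called ran from 18 to 29, 17 to 20 and 25 to 29. The highest genotype counts in culture came without KO replicate 1, CD24+ for the array counts of CD24+ cells and CD172a+ for those of CD172a+ cells. For 196 pairs of a named gene and a comparison, 2596 values with 1 array or mouse left out kept direction and side of the threshold, 235 fell short of it, 6 passed it and 3 reversed, against 1571, 119, 2 and 1 for the other alternatives. All reversals were of Ciita near 0: spleen CD24+ -0.11 without KO replicate 1 and -0.0044 without WT replicate 1, and spleen mice 0.0596 without KO replicate 2 and 0.0596 without the mice that stand apart. They read 0.174 without spleen CD24+ KO replicate 2 and -0.26 without the spleen KO mouse of replicate 1. H2-Ea, near the lower quartile of the arrays in all groups, leaves little loss to be read.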

Other observations

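The tests of explanations in this part were chosen after the results were seen.

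Single metabolic genes were higher in cultured than in spleen cells, a comparison that joins culture, activation and sex. Relative to the median gene, the glucose transporter Slc2a6 was higher by 4.17 in CD24+ and 2.72 in CD172a+ cells, the glycolytic regulator Pfkfb3 by 2.21 and 3.17, and the sterol enzymes Hmgcs1 by 2.64 and 1.91 and Idi1 by 2.37 and 2.76 (n = 4 arrays per side). The lists as wholes were not called with an estimated correlation. As deposited, 11 of 15 members of the glycolysis list were higher and 1 lower in CD24+ cells (11 and 1 adjusted over the list alone, adjusted p = 0.210) and 5 higher and 5 lower in CD172a+ cells (5 and 5, adjusted p = 0.530). Without Pigq, matched through an alias and no glycolysis gene, these were 11 and 0 of 14 (adjusted p = 0.162) and 5 and 4 of 14 (adjusted p = 0.480). Of 14 cholesterol synthesis genes 11 were higher and 2 lower (11 and 2 adjusted over the list alone, adjusted p = 0.350) and 8 and 3 (8 and 3, adjusted p = 0.530). The asparagine synthetase Asns was higher by 3.04 and 2.96, and Lgmn, a lysosomal protease of antigen processing, by 2.96 and 1.91, while Ifi30 was lower by -1.77 and -1.67.

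Single lysosomal proteases of class II processing were lower in spleen CD24+ than CD172a+ cells. Ctsd differed by -1.29 ± 0.08, Ctsl by -1.08 ± 0.11 and Lgmn by -0.90 ± 0.09 (CD24+ minus CD172a+, n = 4 arrays per subset), with 6 of 10 members of the peptide loading list lower and 2 higher (6 and 2 adjusted over the list alone). Of 15 class I presentation genes 10 were higher and 1 lower (10 and 2 adjusted over the list alone), with Tap2 at 0.77 ± 0.08 and Tap1 at 0.65 ± 0.05. The camera calls of these lists (adjusted p = 0.0145 and 0.00636) were lost with an estimated correlation (adjusted p = 0.0898 for both). The complement gene C1qa in spleen CD172a+ cells read 10.6 in WT replicate 2 and 9.83 in KO replicate 2, against 9.25 in WT replicate 1 and 8.70 in KO replicate 1, so it varied more between mice than between genotypes. In spleen CD24+ KO replicate 2, Camp read 10.1 and Car1 10.2, against at most 8.27 and 8.50 in the other 3 spleen CD24+ arrays.

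Of the 4 tested genes nearest to Ciita on chromosome 16 (order from GRCm38.p6), 3 had an unadjusted p under 0.001 in all mice. Tvp23a changed by -0.37 ± 0.06 (adjusted p = 0.213), Dexi by -0.39 ± 0.06 (adjusted p = 0.182) and Clec16a by 0.43 ± 0.06 (adjusted p = 0.188), none past the threshold over all genes, and Nubp1 had no such p (n = 4 mice per genotype). These values average the subsets. In CD24+ cells Dexi gave -0.08 ± 0.09 in spleen and -0.12 ± 0.09 in culture, against -0.50 ± 0.09 and -0.85 ± 0.09 in CD172a+ cells. In the same order Tvp23a gave -0.17 ± 0.12 and -0.28 ± 0.12, against -0.37 ± 0.12 and -0.66 ± 0.12. Clec16a changed in both subsets, by 0.57 ± 0.10 and 0.24 ± 0.10 in CD24+ cells, against 0.53 ± 0.10 and 0.38 ± 0.10. Of 19827 other places in the genome, 3 gave as many, all of them in the class II region on chromosome 17. These neighbours were picked for their values, so the 3 of 4 restates what was seen. The list of 31 neighbours fixed before the data were examined, whose members moved both ways, was called by the mixed test of fry in all mice (adjusted p = 2.830e-05), in spleen CD172a+ cells (adjusted p = 0.00303) and in cultured CD172a+ cells (adjusted p = 9.276e-08), but not in CD24+ cells (adjusted p = 0.0829 and 0.286). Without the 4 nearest genes its unadjusted p in all mice was 0.270. Such a call goes with either explanation, so a local effect of the altered locus and DNA of another strain around Ciita cannot be told apart: of the 36 genes 3 to 20 places away, 3 had an unadjusted p under 0.05, which 31.4% of other places reach, and the breeding history of the mice is not given in the sources used here.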
